A study of Homo sapiens with 9 samples.

How the data were processed

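Peak lists from 9 CUT&RUN libraries of MCF7 cells were used, 2 each for ER in hormone-stripped medium, in hormone-stripped medium with E2, in complete medium with wild-type ESR1 and in complete medium with disrupted ESR1, and 1 for IgG. Groups and replicate numbers came from the sample titles. The submitters' processing notes name Bowtie2 2.3.4.1, deepTools 3.5.0 and MACS2 2.2.7.1 and the builds hg38, sacCer3 and dm6, without saying which step each served. The series' design text states that fly cells and yeast DNA were added as spike-ins. No spike-in counts or reads were used here, so no library was scaled by them. Each deposited list holds, per the file layout, the position, summit, fold enrichment, −log10 p and −log10 q of peaks called in that library alone. The deposited fold enrichment is a ratio of the summit to its local background, and the deposited −log10 q values were all at least 1.3, the level of a q of 0.05. These values are the authors' own and served to rank and filter peaks within a list.

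Coordinates are hg38 and 1-based. Main results used the 24 primary chromosomes. In the ER libraries 3.58% to 31.3% of peaks lay on other sequences, and in IgG 62.4%. Because the deposited fold and −log10 p follow from 2 quantities, the pileup at the summit and the local background, both were recovered by finding the whole-number pileup whose fold and Poisson upper tail matched the pair within a relative tolerance of 0.0001. A match was found for 100% of the peaks. In simulated values, 1940 of 1940 pileups were recovered. The genome-wide background of a library was the lowest local background shared by at least 5 peaks. It scales with sequencing depth times fragment length, so it is not a read total, and pileups divided by it are called scaled. It was lowest in IgG (0.40) and differed between ER groups by a factor of 1.10 for E2 over hormone-stripped, 0.94 for wild type over knockout and 1.13 for complete over hormone-stripped medium, where peak numbers differed by factors of 2.99, 3.28 and 1.02. No read counts were used, so no test of counts per region was possible, and a region without a peak has no value.

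Peaks overlapping by at least 1 bp across the libraries compared were merged into regions. A region belonged to 1 group only if it was called in both libraries of that group and in neither of the other. The number expected from independent calling is the number of merged regions times the product of each library's share of called or uncalled regions. It is taken only over regions called in at least 1 of the compared libraries, so it is not the number expected from random positions on the genome. Peak numbers were compared by an exact permutation test, two-sided, whose smallest p with 2 libraries against 2 is 0.333. Gene positions came from an NCBI RefSeq table on assembly GRCh38.p14, with 20037 protein-coding genes on the primary chromosomes. The table used here carried no strand or exons and no genome sequence was used, so 3 planned steps changed. A gene counted as having a peak in a group when a merged region called in both its libraries (1 for IgG) lay within 20 kb of its span, in place of its transcription start. CCN5, with a peak in each E2 library but no shared region, was therefore not counted. The nearest gene is that with the nearest span. Genomic class is the share of summits inside gene spans. The planned search for estrogen response elements was not run.

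Gene lists of 55 estrogen-induced, 15 estrogen-repressed, 20 luminal, 20 housekeeping, 27 other-cell-type and 15 basal or mesenchymal genes were written before the data were examined, and all their genes were matched. A total of 3 genes belonged to both the estrogen-induced and the luminal list. Fisher's exact test compared each list with all other protein-coding genes, with Benjamini-Hochberg adjustment over 30 tests. Differences between groups within a list were tested by the exact McNemar test, adjusted over 12 tests, and again, chosen after seeing the data, with genes dropped that had a peak in 1 library of the other group. Random lists matched on the decile of gene length (10000 draws) served as a check chosen after seeing the data. In simulated data, all 1350 planted regions were put in their class, and 2.5% of 1000 random lists had a p below 0.05.

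Replicate overlap was set against 1000 random placements of each peak on its chromosome. Intervals of shares are Wilson 95% intervals and cover counting error only. Named regions were fixed by rule before the data were examined. They were the 10 highest-ranked regions of each first group and the 3 of each reverse set (by the lower of the 2 libraries' percentiles of −log10 q), the 5 highest-ranked regions called in all 8 ER libraries, up to 20 estrogen-induced genes with a region in both E2 libraries, up to 4 genes of each other list, the genes ESR1, GREB1, TFF1, PGR and FOXA1, and the 3 bins of 1 Mb with most peaks. KRT8, KRT19, CCN5, ACSL3, ACTB and the further regions of the closing part were named after their values were seen. Alternatives covered stricter q and fold limits, removal of IgG-overlapping peaks, all sequences, equal list lengths, other overlap rules, windows of 5 and 100 kb, and each library left out in turn. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.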

Results

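Estrogen receptor (ER) binding was profiled by CUT&RUN, an assay in which an antibody directs a nuclease to cut out the DNA under its target protein, in MCF7, an ER-positive human breast cancer cell line that depends on estrogen for growth. The 9 libraries comprised 4 ER groups of 2 libraries each and 1 IgG library. MCF7 cells, for which the sample titles name no ESR1 genotype, were kept in hormone-stripped (charcoal-treated) medium without or with estradiol (E2). Cells in complete medium were either wild type or carried a CRISPR disruption of ESR1, the gene that encodes ER. The IgG antibody, which has no specific target, was applied to wild-type cells in complete medium. Lists of peaks called separately in each library were analysed, 6595 peaks in all. Read totals were not given in the sources used here, so depth was judged from the genome-wide background coverage recovered from the peak values, which was 0.585 and 0.572 fragments in the hormone-stripped libraries, 0.679 and 0.597 with E2, 0.678 and 0.631 in the wild-type libraries, 0.680 and 0.718 in the knockout libraries and 0.40 in IgG. The smallest summit pileup that was called, meaning the number of fragments stacked at the summit, was 6 or 7 in the ER libraries and 5 in IgG, so a region without a peak was below the calling limit and not necessarily unbound. That limit rose with the local background, so a missing call can hide a taller pileup where the background was high. The labels did not say whether replicates came from separate cultures, and p-values across libraries therefore measured only the spread between these libraries.

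The first comparison asked where ER binding differed when E2 was added to hormone-stripped medium. With E2, 629 regions were called in both libraries and in neither hormone-stripped library, whereas 12 regions showed the reverse. They included regions at GREB1 and near TFF1, 2 genes of the estrogen-induced list described below. At GREB1, a growth regulator induced by estrogen, a region on chromosome 2 (11532177 to 11532932, hg38) reached a summit pileup of 53.0 ± 1.41 fragments (SD, n = 2) with E2. A region 9671 bp from TFF1, which encodes a secreted trefoil peptide, lay within the span of the neighbouring gene TMPRSS3 on chromosome 21 (42376206 to 42376971) and reached 48.0 ± 5.66 fragments. No peak was called within 20 kb of either gene in the hormone-stripped libraries.

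Among the 10 highest-ranked E2-only regions, the first lay on chromosome 8 (97764042 to 97764749), 11039 bp from LAPTM4B, and had a summit pileup of 98.5 ± 10.6 fragments (SD, n = 2). The next were a region 71981 bp from the growth factor gene FGF3 on chromosome 11 (69891397 to 69892172; 83.0 ± 4.24 fragments), one inside ASB13 on chromosome 10 (5659747 to 5660677; 73.0 ± 1.41) and one inside TENM4 on chromosome 11 (79059683 to 79060611; 99.0 ± 7.07). A region 6887 bp from IER3, an immediate early response gene, on chromosome 6 (30751434 to 30752529) had 66.5 ± 6.36 fragments, and one inside the apoptosis gene CASP7 on chromosome 10 (113678585 to 113679474) had 63.0 ± 1.41. A region 16070 bp from CYP24A1, which encodes a vitamin D hydroxylase, on chromosome 20 (54126950 to 54127468) had 113 ± 4.24 fragments. Its local background was high, since 31 fragments in wild-type replicate 2 made a fold of only 2.60, so a missing call there can hide a taller pileup than elsewhere. The remaining regions lay near REEP3 (46.0 ± 1.41), near PRAG1 (51.0 ± 5.66) and inside GREB1. The 3 highest-ranked regions of the reverse set were smaller, with 11.5 ± 2.12 fragments inside ABCC10, 10.5 ± 0.707 beside CACTIN and 26.0 ± 5.66 inside CSDE1 in the hormone-stripped libraries.

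**Figure D1:**
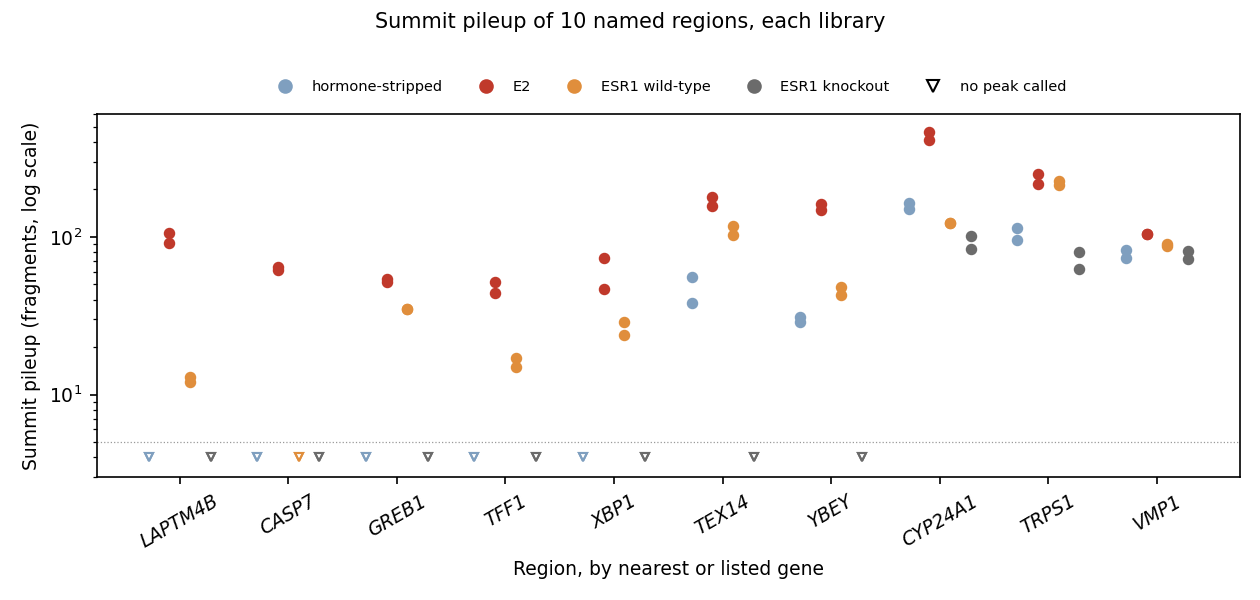
Summit pileup in fragments, on a log scale, of 10 named regions (horizontal axis) in each of the 8 ER libraries. Filled circles are libraries with a peak and open triangles below the dotted line mark libraries in which no peak was called. The height of the triangles is not a value, and the calling limit was higher where the local background was high, as at TEX14. The GREB1 and TFF1 regions had peaks with E2 and in wild-type cells in complete medium and none in the hormone-stripped or knockout libraries, while the VMP1 region stayed between 72 and 105 fragments in all 8.

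E2 libraries held 1553.5 ± 255 peaks on the primary chromosomes (SD, n = 2) and hormone-stripped libraries 520 ± 136, a ratio of 2.99. Each E2 library, with 1373 and 1734 peaks, exceeded each hormone-stripped library, with 424 and 616. The exact permutation test gave a two-sided p of 0.333, the smallest that 2 libraries against 2 allow. Over all 2524 merged regions, independent calling at the same list lengths would give 593 E2-only and 14.7 hormone-stripped-only regions. Whether E2-only regions exceeded that number depended on the setting, with 500 against 506 at a −log10 q of at least 5. Without hormone-stripped replicate 1 or 2 there were 670 against 738 and 741 against 841. Without E2 replicate 1 or 2 there were 1307 against 991 and 1020 against 708. With 1 E2 library left, however, every merged region without a hormone-stripped call was necessarily E2-only. That rule favours an excess, so these 2 settings cannot decide. The expected numbers cover only regions called in at least 1 of these libraries, so they do not show what random positions would give. With random placement, a mean of 0.823 peaks of E2 replicate 1 overlapped E2 replicate 2, against 943 found. When the same number of peaks was taken from each library, 207 regions were E2-only and 80 hormone-stripped-only, against 60.4 and 59.4 under independent calling. At the 159 regions called in all 4 libraries, the summit pileup scaled by background was higher with E2 in 121, with a median log2 ratio of 0.28 (interquartile range 0.02 to 1.04). Over the 4 pairs of an E2 and a hormone-stripped library that median had an SD of 0.19. With equal list lengths 76 such regions were left, with a median of 0.98. That setting kept the highest-ranked peaks and shortened the E2 lists most. It therefore favours regions tall with E2 and cannot show that the change was larger.

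**Figure D2:**
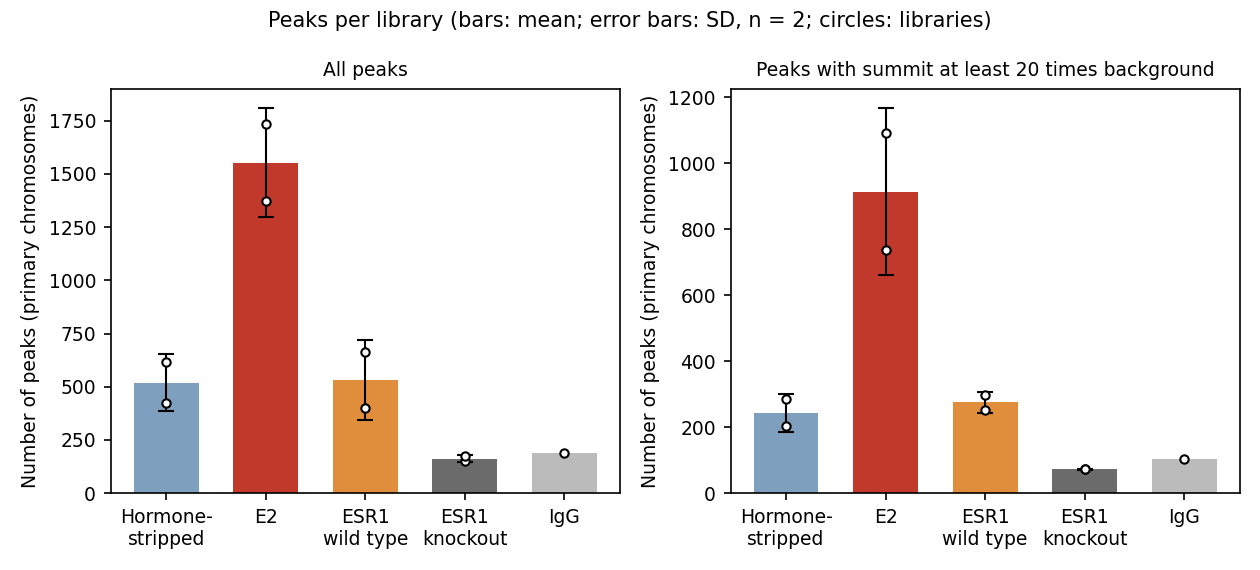
Number of peaks on the primary chromosomes per library (vertical axes) in the 5 groups, for all peaks (left) and for peaks whose summit was at least 20 times the background coverage (right); bars are means, error bars SD (n = 2) and circles libraries, with 1 library for IgG. The E2 libraries, with 1373 and 1734 peaks, lay above every other library in both panels.

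Estrogen-induced genes, a list of 55 known ER targets fixed before the data were examined, had a region called in both E2 libraries within 20 kb in 18 cases (32.7%), against 4.79% of the 19982 other protein-coding genes (odds ratio 9.67, Fisher's exact test, adjusted p = 1.57e-09 over 30 tests of 6 lists in 5 groups, 2.62e-10 adjusted over the list alone). The same rule, 1 region called in both libraries of a group, was met by 10 of 20 luminal genes, which mark the epithelial lineage of MCF7 (odds ratio 19.7, Fisher's exact test, adjusted p = 8.41e-08), and 3 of the genes with a peak, MYB, RARA and XBP1, also stood in the estrogen-induced list. In hormone-stripped medium 3 genes of the estrogen-induced list met it, CYP24A1, FKBP4 and MREG (Fisher's exact test, adjusted p = 0.194), and this list passed the test at a −log10 q of at least 5 (adjusted p = 0.0295) and with equal list lengths (0.0271), in a range over all alternatives of 0.0271 to 0.790. Between the groups, 15 estrogen-induced genes met the rule only with E2 and 0 only without (exact McNemar test, p = 6.1e-05, adjusted p = 0.000732 over 12 tests), and among luminal genes the numbers were 8 and 0 (exact McNemar test, adjusted p = 0.0313). Leaving out genes with a peak in 1 hormone-stripped library, which were ABHD2, CISH and FOS among the 15 and KRT19 among the 8, the numbers were 12 and 0 (exact test, adjusted p = 0.00586) and 7 and 0 (adjusted p = 0.0625), so the luminal difference did not pass in this check, chosen after seeing the data. Genes outside the estrogen-induced list that met the rule also rose, from 1.52% in hormone-stripped medium to 4.79% with E2. The tests between groups were against no change, so they cannot set these lists apart from that general rise. Genes served as the units of all tests of lists, so they describe these libraries and not the spread between cultures.

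The estrogen-induced genes with a region called in both E2 libraries ranged widely in summit pileup. CYP24A1 had the tallest, a region 19340 bp from the gene with 438 ± 34.6 fragments with E2 and 158 ± 10.6 without (SD, n = 2), in a part of chromosome 20 where IgG also had a peak near the gene. At MREG, the pileup was 59.5 ± 0.707 with E2 and 27.5 ± 2.12 without. XBP1, a transcription factor of secretory cells, had 60.0 ± 18.4 fragments, NHERF1 44.0 ± 1.41, CISH 43.5 ± 4.95, SIAH2 36.5 ± 3.54, TSKU 36.5 ± 2.12 and IGFBP4, an insulin-like growth factor binding protein, 32.0 ± 4.24. SGK3, RARA, TPD52L1 and FOS had between 22 and 27.5 fragments. The lowest were ABHD2, CA12, FKBP4 and MYB, with 20 ± 2.83, 19.5 ± 3.54, 13.5 ± 0.707 and 9.5 ± 0.707. Of these 18 genes, ABHD2, CISH and FOS had a peak within 20 kb in 1 hormone-stripped library, and CYP24A1, FKBP4 and MREG in both. At ABHD2 and FKBP4 those peaks lay outside the regions whose pileups are given here, which no hormone-stripped library called.

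Luminal genes with a peak in both E2 libraries included XBP1, KRT18 (37.5 ± 12 fragments), GRHL2 (29.5 ± 3.54), PBX1 (21.5 ± 0.707) and ESR1 itself. Of 15 estrogen-repressed genes, 3 had such a peak, NR5A2, HES1 and BCAS1 (Fisher's exact test, adjusted p = 0.158), and BCAS1, which lies in the same part of chromosome 20 as CYP24A1, also had an IgG peak within 20 kb. Among 20 housekeeping genes only GAPDH had one, among 27 markers of other cell types INS, SYP and SNAP25, and among 15 basal or mesenchymal genes TP63, and no list of these 3 passed Fisher's exact test (adjusted p from 0.387 to 1). The INS region overlapped TH, its neighbour. FOXA1, a pioneer factor of ER binding, had a peak in 1 E2 library only, and PGR, the progesterone receptor gene, had none within 20 kb in any library.

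**Figure D3:**
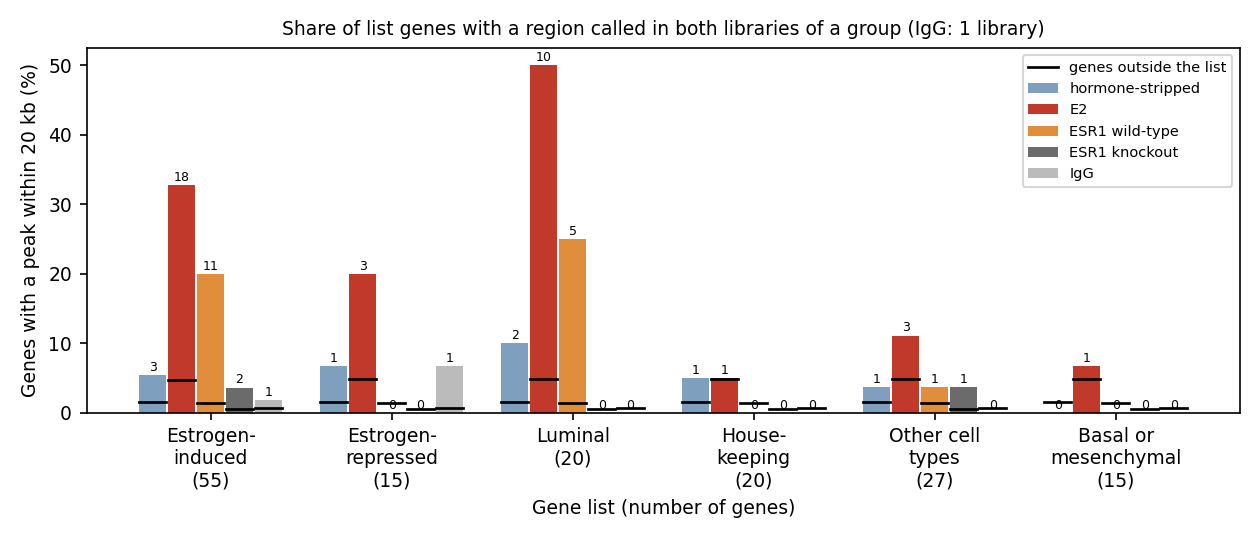
Percent of the genes in each of 6 lists (horizontal axis, number of genes in brackets) with a peak within 20 kb, by group; bars carry the number of genes, the black lines give the percent among genes outside the list, and in an ER group 1 region had to be called in both libraries. Estrogen-induced and luminal genes stood above the other genes with E2 (32.7% and 50%, against about 4.8%) and in wild-type cells in complete medium.

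The second comparison asked how the ER signal in complete medium differed between wild-type cells and cells with disrupted ESR1. At the ESR1 gene (chromosome 6, 151656672 to 152129619) a peak was called near its start coordinate in 1 wild-type library, with a summit pileup of 16 fragments, and in neither knockout library, but a peak list cannot show whether the gene was disrupted. In wild-type cells 150 regions were called in both libraries and in neither knockout library, and 7 regions showed the reverse. GREB1 (35.0 ± 0.00 fragments, SD, n = 2) and TFF1 (16 ± 1.41) had peaks in both wild-type libraries and none within 20 kb in either knockout library. TEX14, on chromosome 17 (58639458 to 58640608), held the highest-ranked wild-type-only region, with 110 ± 9.90 fragments in wild-type cells in complete medium and 168.5 ± 16.3 with E2. Its local background was high, since 38 fragments in hormone-stripped replicate 1 made a fold of only 3.28, so the missing knockout calls can hide a taller pileup than elsewhere.

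The other highest-ranked wild-type-only regions lay 232412 bp from TNP1 on chromosome 2 (217092476 to 217092991; 42.5 ± 7.78 fragments), 6951 bp from IER3 (47.0 ± 7.07), inside YBEY on chromosome 21 (46292544 to 46294801; 45.5 ± 3.54), 70872 bp from BOD1 on chromosome 5 (173535311 to 173536273; 53.5 ± 3.54) and inside SEPTIN9 on chromosome 17 (77286745 to 77287264; 51.0 ± 2.83). Regions near CFAP58 (36.0 ± 4.24) and MED13L (36.5 ± 7.78) and inside TMEM120B (40.5 ± 2.12) and GAB2 (37.5 ± 0.707) completed the 10. All 10 were also called in both E2 libraries, and the IER3, CFAP58 and TMEM120B regions in no hormone-stripped library. The 3 highest-ranked knockout-only regions, inside SCYL3 (11.0 ± 0.00), RNF167 (14.5 ± 3.54) and ERCC6L2 (15.5 ± 3.54), were small and were each called in hormone-stripped medium as well.

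**Figure D4:**
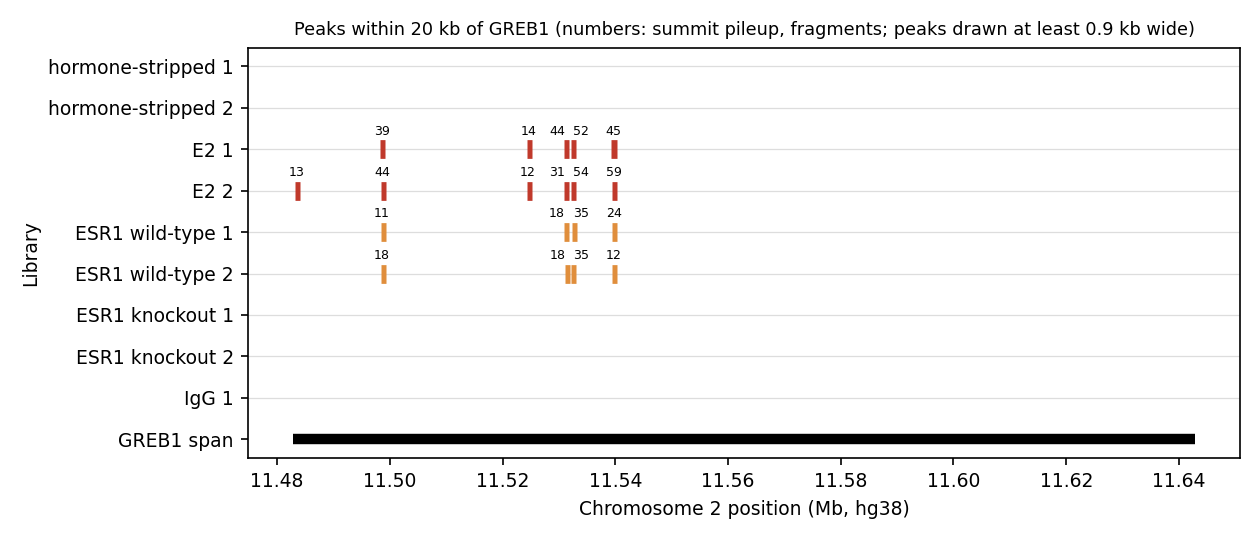
Peaks within 20 kb of GREB1 in each of the 9 libraries (vertical axis) along chromosome 2 (horizontal axis, Mb, hg38), with the summit pileup in fragments above each peak and the gene span as a black bar. Peaks were called in the E2 libraries (5 and 6) and in the wild-type libraries in complete medium (4 and 4), and in none of the hormone-stripped, knockout or IgG libraries.

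Wild-type libraries in complete medium held 532.5 ± 187 peaks (SD, n = 2; 665 and 400) and knockout libraries 162.5 ± 14.8 (152 and 173), a ratio of 3.28 (two-sided exact permutation p = 0.333, the smallest possible). IgG gave 189 peaks, more than either knockout library, but at a −log10 q of at least 5 it gave 32, against 67 and 52 in the knockout libraries. Independent calling at these list lengths would give 190 wild-type-only and 4.99 knockout-only regions among the 967 merged regions, each called in at least 1 of the 4 libraries. This was more wild-type-only regions than the 150 found, but again not a number expected from random positions. Without wild-type replicate 1 or 2 there were 312 against 209 and 534 against 424 expected. With 1 wild-type library left, however, every merged region without a knockout call was necessarily wild-type-only. That rule favours an excess, so these settings cannot show that the direction turned. When the same number of peaks was taken from each library, 56 regions were wild-type-only and 16 knockout-only, against 21.6 and 21.8 under independent calling. At the 38 regions called in all 4 libraries the scaled summit pileup was higher in wild-type cells in 35, with a median log2 ratio of 0.50 (interquartile range 0.32 to 0.91) and an SD of that median over the 4 library pairs of 0.11.

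In wild-type cells in complete medium, 11 of the 55 estrogen-induced genes had a region called in both libraries (odds ratio 17.4, Fisher's exact test, adjusted p = 5.7e-09), among them CISH, GREB1, RARA, SGK3, SIAH2, TFF1, TSKU and XBP1. In knockout cells there were 2, CYP24A1 and FKBP4 (Fisher's exact test, adjusted p = 0.158). In total, 9 genes met this rule only in wild-type cells and 0 only in knockout cells (exact McNemar test, adjusted p = 0.0234). One of the 9, MREG, had a peak in 1 knockout library, and without it the numbers were 8 and 0 (exact test, adjusted p = 0.0469). Genes outside the list differed too, with 1.42% meeting the rule in wild-type and 0.49% in knockout cells. The tests between groups, which were against no change, cannot set the list apart from that general difference. Luminal genes with a peak numbered 5 of 20 in wild-type cells, KRT8, KRT18, PBX1, RARA and XBP1 (Fisher's exact test, adjusted p = 6.38e-05), and 0 in knockout cells, a difference that did not pass the test after adjustment (exact McNemar test, adjusted p = 0.188). Of these genes, RARA and XBP1 also stood in the estrogen-induced list. KRT8 and KRT18 had peaks in the same libraries throughout, so they may not count as separate. Without the knockout replicate 2, the estrogen-induced list had 4 genes with a knockout peak and passed Fisher's exact test (adjusted p = 0.0236).

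Next, it was asked whether regions gained with E2 depended on ESR1 in complete medium. Of the 629 E2-only regions, 184 were called in at least 1 wild-type library, and 8 of these (4.35%) also in a knockout library. Of the 159 regions called in all 4 libraries from stripped medium, 135 had a wild-type call, and 78 of these (57.8%) also had a knockout call (Fisher's exact test between the sets, odds ratio 0.0332, two-sided p = 6.01e-28). The E2-only regions were lower in wild-type cells, with a median of 13 fragments against 22, and so closer to the calling limit. Within deciles of the wild-type pileup, a comparison chosen after seeing the data, the 8 knockout calls stood against 36.3 expected at the same height (permutation p = 0.0001, the smallest possible). Between 16 and 40 fragments, knockout calls numbered 2 of 63 and 43 of 74. The 2 sets were chosen by the absence or presence of calls in the hormone-stripped libraries. They may therefore differ in how readily any library with few peaks calls them. Matching on the wild-type pileup does not remove this, so these tests cannot show that ESR1 itself was the reason. The GREB1, TFF1, XBP1, TENM4 and IER3 regions were E2-only with a wild-type and no knockout call, and the CYP24A1 region with 438 fragments was called in all 8 ER libraries.

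Taken over all E2-only regions, 176 of 629 (28%) had a wild-type call and no knockout call, against 13.5% of the 1895 other merged regions (Fisher's exact test, odds ratio 2.49, p = 1.4e-15). Most of those other regions, 1415, were called in 1 library only. Against the 480 others called in at least 2 libraries, of which 37.3% had a wild-type and no knockout call, the direction turned (Fisher's exact test, odds ratio 0.653, p = 0.00115, a comparison chosen after seeing the data). It also turned when either E2 library was left out (16% against 24.5%, and 19.2% against 24.5%). Regions called in 1 E2 library then counted as E2-only, and every other region had a hormone-stripped call. The sets compared thus changed, so this turn does not show dependence on a replicate.

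Wild-type cells in complete medium, which contains serum hormones, were set against the cells in hormone-stripped medium. Peak numbers were 532.5 ± 187 and 520 ± 136 (SD, n = 2; two-sided exact permutation p = 1), a ratio of 1.02. At a −log10 q of at least 5 they were 264.5 ± 14.8 and 180.5 ± 44.5, a ratio of 1.47, and both complete-medium libraries exceeded both hormone-stripped libraries (lowest ratio over pairs 1.20; exact permutation p = 0.333, the smallest possible). Of the genes in the lists, GREB1, TFF1, SIAH2, TSKU, RARA, XBP1, SGK3 and PBX1 had a peak in both libraries in complete medium and none in stripped medium. ACTB, a housekeeping gene, showed the reverse. No test of genes was made between these media. Peaks of the wild-type libraries overlapped peaks of the E2 libraries more often, in 54.1% to 81.8% of cases, than peaks of the hormone-stripped libraries, in 26.9% to 44.0%, although the E2 lists were also longer.

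Some regions were called in every ER library. Of 2869 merged regions, 34 had a peak in all 8 ER libraries, and 1 of these, inside ACSL3, also overlapped an IgG peak. A region 197910 bp from TRPS1, which encodes a GATA-type repressor of luminal cells, on chromosome 8 (115866885 to 115868095) had 104.5 ± 13.4 fragments in stripped medium, 233.5 ± 23.3 with E2, 220.5 ± 7.78 in wild-type and 71.5 ± 12 in knockout cells in complete medium (SD, n = 2). A region 38490 bp from CYP2A7 on chromosome 19 (40920721 to 40921882) had 156 ± 19.8, 265.5 ± 0.707, 93.0 ± 4.24 and 30.5 ± 9.19 fragments in the same order. At VMP1 on chromosome 17 (59837349 to 59837831), values were 78.5 ± 6.36, 105 ± 0.00, 89.0 ± 1.41 and 77.0 ± 7.07, a narrower range. Folds over the local background there were only 5.52 to 9.72, against 33.4 to 138 at the TRPS1 region, so the VMP1 pileups stood on a high local background. Regions inside PGBD2 and 21825 bp from RNASE12 also varied little between wild-type and knockout cells, with scaled ratios of 1.19 and 0.96.

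Replicates shared 30.1% to 68.7% of their peaks, where random placement on the same chromosomes gave at most 0.0599%. The share was highest between the E2 libraries (68.7% and 54.4%), and lowest between the knockout libraries (34.2% and 30.1%; Wilson 95% intervals 27.1 to 42.1 and 23.7 to 37.3). On average, knockout peaks overlapped each other (32.1%) less than hormone-stripped (53.2%), E2 (61.7%) or wild-type peaks (46.8%), whose lists were longer. Hormone-stripped and wild-type peaks overlapped their own replicate (40.9% and 46.8%) less than the longer E2 lists (55.0% and 68.5%). Summits lay inside protein-coding gene spans in 46.8% to 50.7% of the peaks of the ER libraries and in 48.7% of IgG peaks. Peaks of the ER libraries overlapped an IgG peak in 0.437% to 4.62% of cases, where random placement gave at most 0.0145%.

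By chromosome, IgG peaks gathered on chromosome 20, with 52 of 189 (27.5%), and chromosome 17, with 28. Chromosome 20 held 4.44% to 6.47% of the peaks in 7 ER libraries and 11.6% in knockout replicate 2. The 3 bins of 1 Mb with most peaks began at position 8000001 of chromosome 17, with a mean of 5.75 peaks per ER library and 0 in IgG, and at 47000001 and 53000001 of chromosome 20, with means of 5.5 and 4.25 and with 13 and 12 IgG peaks. The CYP24A1 and BCAS1 regions fell close to the last of these bins, so their peaks lay in a part of the genome with raised IgG signal.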

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

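Of 269 recomputed values, 222 kept their direction and side of the threshold (counts of regions were held only to a change within 1.5 times, not to their expected number), but 14 of the peak-number ratios and gene counts among these moved by more than 1.5 times. The E2 peak-number log2 ratio (1.58) was 2.39 at a −log10 q of at least 5. Estrogen-induced genes with a region in both E2 libraries (18) numbered 9 with equal list lengths and 36 at 100 kb, and those near E2-only regions (15) 32 at 100 kb. In hormone-stripped medium (3) there was 1 at 5 kb, 6 with at least 1 library and 5 without replicate 1. In wild-type cells (11) there were 18 with at least 1 library, and near wild-type-only regions (9) 14 without wild-type replicate 1. In knockout cells (2) there were 4 with at least 1 library and 1 at the stricter q, the stricter fold, with the summit filter and without chromosomes 17 and 20. The summit filter at 20 times background, the removal of chromosomes 17 and 20 and the comparison with regions called in at least 2 libraries were chosen after seeing the data, as was the count of genes with no peak in either library of the other group (luminal, E2 against stripped, 7 against 8, exact adjusted p = 0.0625 against 0.0313). The log2 ratio of peak numbers in complete against hormone-stripped medium (0.03) changed sign to -0.028 with all sequences and ranged from -0.38 to 0.35 without single libraries, while at the stricter q it was 0.55, so it depended on the setting. With equal list lengths, E2-only regions numbered 207 and hormone-stripped-only 80, wild-type-only 56 and knockout-only 16, where independent calling would give 60.4, 59.4, 21.6 and 21.8. Hormone-stripped-only regions (12) numbered 5 at a −log10 q of at least 5, 7 at a fold of at least 5 and 5 with the summit filter. Knockout-only regions (7) numbered 2 at that q, 4 with summits within 200 bp and 0 with the summit filter. Without single libraries, where a region needed 1 library in that group, E2-only regions ranged from 670 to 1307, hormone-stripped-only from 20 to 229, wild-type-only from 166 to 534 and knockout-only from 8 to 85. The share of E2-only regions with a wild-type and no knockout call ranged from 16% to 31.7% without single libraries; its direction against other regions reversed without either E2 library and against regions called in at least 2 libraries (28% against 37.3%).

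The median log2 pileup ratio at regions called in all libraries moved from 0.28 to 0.48 (fold of at least 5) and 0.98 (equal list lengths) for E2, and from 0.50 to 0.62 and 0.67 for wild type against knockout. Equal list lengths left 76 and 28 regions and shortened the E2 and wild-type lists most, which favours regions tall in those groups. Without single libraries it ranged from 0.14 (without E2 replicate 2) to 0.45 for E2, and from 0.44 to 0.56 for wild type against knockout. The share of summits inside genes (49.0%) was 46.6% at the stricter q, 42.1% with all sequences, 46.7% with equal list lengths and 45.8% with the summit filter. The 3 estrogen-induced genes with a peak in hormone-stripped medium passed the threshold at the stricter q (Fisher's exact test, adjusted p = 0.0295) and with equal list lengths (3 genes, adjusted p = 0.0271). In knockout cells there were 0 such genes with a window of 5 kb and between 2 and 4 without single libraries. For IgG the number was 0 at the stricter q, at the stricter fold, with equal list lengths and without chromosomes 17 and 20, and 1 with a window of 100 kb, all on the other side of the genome-wide rate. A peak near FOXA1 was called in 0 ER libraries at the stricter q or fold and in 2 with a window of 100 kb, against 1. Under the replicate block, with same-numbered libraries taken as pairs, the log2 ratios of peak numbers were 1.59, 1.67 and 0.01 for E2, wild type against knockout and complete against stripped medium, and the block leaves the counts of regions as they are.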

Other observations

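The test of local backgrounds in the last paragraph was chosen after the values had been seen, as were the limit of 40 times the background, the height-adjusted and Pearson correlations and the length-matched lists.

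Regions called in all 8 ER libraries differed in their ratios between groups. Regions inside EPS15L1, RBM20 and EBAG9 and 37598 bp from DYRK1A, named after their values were seen, had wild-type pileups 5.18, 3.01, 2.69 and 2.76 times those of knockout cells after scaling by background, and the E2 libraries were 2.50, 3.16, 1.61 and 3.65 times the hormone-stripped ones. Regions inside RPS19 or within 66 bp of TOMM40, PRMT5 and ANKRD17, chosen in the same way, had E2 to hormone-stripped ratios of 1.08, 1.08, 1.17 and 0.70 and wild-type to knockout ratios of 1.37, 1.59, 1.32 and 1.42. Others did not follow either kind, since regions 221138 bp from ZPLD1, inside KCTD2 and 13044 bp from GNGT2 had E2 ratios of 0.95, 1.00 and 0.79 with wild-type to knockout ratios of 2.03, 1.89 and 1.86, and that near CYP24A1 had 2.54 and 1.41. With gene lists matched on length, chance gave a mean of 2.84 estrogen-induced genes with a peak in the E2 libraries and at most 10 in 10000 draws, against 18 observed (permutation p = 0.0001, the smallest possible).

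More peaks were called with E2 than in hormone-stripped medium. Sequencing depth as the whole cause is argued against by taller peaks, since 3.76 times as many E2 peaks reached 20 times the background (11.4 to 13.6 fragments, where the smallest called had 6 or 7), with a lowest ratio over pairs of libraries of 2.59. At 40 times the background the ratio was 4.53 (lowest 2.94). A yield difference common to all regions predicted an equal change at regions with and without knockout calls. The median log2 ratio of scaled pileup was 0.14 at 40 regions called in both knockout libraries and 0.48 at 70 called in neither, a difference of 0.34 (95% bootstrap interval 0.06 to 0.72). This cannot decide, because the local background was not subtracted from the pileups. Regions with more local background would show a smaller ratio even under a common yield change. A change in ER binding with E2, as the design intends, stays as a hypothesis, and a yield difference stays open beside it.

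A total of 52 regions were still called in both knockout libraries. E2-dependent binding by ER left in these cells as the only source predicted E2-only regions at least as often as among wild-type-only regions. Instead 0% were E2-only, against 46.7% of the wild-type-only regions (Fisher's exact test, p = 3.09e-12), and 82.7% were called in both hormone-stripped libraries. This cannot decide, because weak remaining binding would be called only at the strongest sites. Such sites can also be called without E2, as those inside EPS15L1 and RBM20 were, with E2 to hormone-stripped ratios of 2.50 and 3.16. Raised local background as the only source is argued against, since 11.5% (Wilson 95% interval 5.4 to 23) had a background above 5 times the genome-wide level in both libraries. ER-independent signal as the only source stays open. The planned test set the E2 ratio against the wild-type to knockout ratio over the 34 regions called in all 8 libraries (Spearman's rho 0.38, permutation p = 0.0314; 0.32, p = 0.0679, with mean height held fixed; Pearson's r 0.59, p = 0.0005), but it cannot decide, because ER binding added in the E2 and wild-type libraries on top of ER-independent signal would raise both ratios as well. Binding by ER without hormone stays open too.

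Local backgrounds relative to the genome-wide level at summits within 15 bp of each other had a median Spearman's rho of 0.98 over the 28 pairs of ER libraries (across regions, lowest 0.74), and agreed within 10% at a median of 87.9% of the summits (lowest pair 55.2%). One candidate explanation is that the same control library, for which the IgG library labelled as input is one possibility, entered all ER peak calls. A background taken from the library itself would be raised under a tall peak, yet 11 of 310 peaks with at least 50 fragments had a local background within 1% of the genome-wide level. If so, the low overlap of ER and IgG peaks may in part follow from the calling and would be no independent measure of specificity. No biological explanation was tested for this pattern.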
